A study of Oryza sativa with 51 samples.

How the data were processed

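Messenger RNA was measured by strand-specific RNA sequencing in flag leaves, the last leaves formed before the panicle, of field-grown rice at grain filling. The 51 libraries cover 3 lines: LY2186, a hybrid, its male-sterile parent SE21s and its restorer parent MH86. Each line has 17 libraries, taken every 3 h from Zeitgeber time (ZT) 0 to 48, with 1 library per line and time. The labels do not give the light schedule, and they do not say whether libraries of a line come from separate plants. P-values of single genes therefore measure the spread between these libraries, which may be technical. In level comparisons that spread also holds differences between lines in the daily curve. In rhythm tests it also holds departures from the fitted 24 h curve.

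The authors deposited 1 table of FPKM values (fragments scaled to transcript length and library size) for 34653 gene identifiers, of which 34570 are rice locus identifiers and 83 belong to unplaced sequence. Per the submitters' processing notes, TopHat2 and Cuffdiff were used, in versions not given in the sources used here. The genome build, the annotation release and the treatment of fragments that map to several places are not given in the sources used here. Fragment counts were not analysed here, so the depth per library is unknown and no counting intervals are given. Low values in the table place the relative depths between 1 and 2.73 times that of the first SE21s library. FPKM sums ran from 824871 to 2467820 per library. The top 3 loci, LOC_Os06g47230, LOC_Os02g27769 and LOC_Os04g32710, took 24.6% to 68.6% of these sums, while the upper quartile of FPKM lay between 9.125 and 10.68. The deposited scaling was therefore kept, and other scalings were tried as alternatives.

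The deposited table does not pair identifiers with gene names, and the reference gene table (assembly ASM3414082v1) matched 0 of them. No coordinates are printed, because the build of the table is not stated. Before the data were examined, 15 gene lists with 151 members were fixed by locus identifier, with symbols assigned from general knowledge of rice genes. All 151 were in the table, and 128 passed the expression filter. Results of 1 member are not reported here, though it is counted in its list. A pair of the lists holds markers of grain and floral organs, which could enter a leaf sample. The rule for named genes, also set before the data were examined, takes every tested clock gene in the rhythm comparisons and, in each comparison, up to 4 members of every other list with the smallest adjusted p. A gene outside these rules is said to have been chosen after its values were seen. Of genes outside the lists, at most 2 identifiers in each direction are given per comparison.

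Values were analysed as log2(FPKM + 0.5) for the 16842 genes with a mean of at least 1 FPKM over all libraries. Fold changes are on this scale and understate the change of low genes. Models were fitted with limma 3.58.1 in R 4.3.3, with a trended and robust variance prior, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Rhythm was tested in each line with a 24 h cosine and sine term, which gave a peak time and an amplitude. Levels were compared with time point as a block, so that each line is set against another at the same 17 times. The contrast with the mid-parent sets LY2186 against the mean of the parents on the log2 scale. Rhythm differences were tested with line by cosine and line by sine terms beside the time block. This test covers amplitude and peak time together, so its p does not test a peak shift alone. A gene called above or below both parents passed both hybrid contrasts in that direction.

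Amplitude and peak time over all genes were compared in 7370 genes with a pooled rhythm of at least 2-fold from trough to peak. The median difference was tested by swapping the line labels within time points in 100 draws, so the smallest p is 0.0099. Gene lists were tested with Fisher's exact test for rhythm and with camera for levels, first with a preset correlation of 0.01 between genes and then with an estimated one. List p-values were adjusted over the 15 lists of a comparison. Fisher's exact test takes genes as independent and uses no spread between libraries. In the level comparisons the estimated correlation was 0.71 for antenna and 0.36 for chlorophyll synthesis genes. Fisher p-values may therefore be too small. Counts of list members are given over all genes tested and adjusted over the list alone.

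Some abundant genes are listed at exactly 0 in single libraries between high values. An exact 0 in such a file can be a failed estimate. A 0 was called doubtful where at least 2 of the neighbouring times and the same hour of the other day of that line reached 10 FPKM, which marked 483 values in 129 genes. They were kept as deposited, and 2 alternatives that remove them were added after seeing the data.

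The steps were tested on simulated data with the 16842 genes. Noise was drawn independently for each gene and library, rhythms were exact cosines, and 100 genes were changed per effect size. In the rhythm test, 41% to 50% of 2-fold rhythms and 84% to 85% of 4-fold rhythms were recovered, with at most 3.08% false calls. In the level test, 61% to 72% of log2 changes of 0.5 and 90% to 94% of changes of 1 were recovered, with at most 7.78% false calls. In the rhythm-difference test, where every gene had a 4-fold rhythm, 7% to 18% of peak shifts of 1.5 h and 51% to 60% of shifts of 3 h were recovered, with at most 6.02% false calls. In the deposited data genes vary together and curves depart from a cosine, so these rates may not carry over. The alternatives changed the pseudocount, the expression filter, the scaling, the time block, the curve, the days used, the minimum fold and the correlation in camera, and left out each time point in turn. Figures were drawn with matplotlib 3.10.9.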

Results

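The data follow the flag leaf transcriptome of the rice hybrid LY2186 and its parents, MH86 (the restorer) and SE21s (which is male-sterile), through 48 h in the field at grain filling. There were 17 libraries per line, 1 every 3 h. Between 15532 and 16629 genes reached 1 FPKM in a library, and the number of fragments behind each value is unknown. Libraries of a line taken 24 h apart had a median correlation across genes of 0.96, and those taken 12 h apart 0.803 (genes are not independent replicates). The first 3 principal components held 29.3%, 23.5% and 17.8% of the variance. The series asks how daily gene expression differs between the hybrid and its parents.

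The first question was which genes cycled in each line. Fitted peaks of clock genes were spread through the day in all 3 lines. LHY, a MYB repressor of the morning part of the clock, peaked at 0.223 ± 0.08 h in SE21s, 1.23 ± 0.11 h in LY2186 and 1.77 ± 0.16 h in MH86 (fitted peak ± SE, 17 libraries each). The pseudo-response regulators PRR95, PRR37 and PRR73 had fitted peaks at 7.25 ± 0.23 h, 7.94 ± 0.36 h and 8.05 ± 0.36 h in SE21s, and within 0.34 h of these times in LY2186 and MH86. PRR59 peaked before them in LY2186 (5.77 h) and MH86 (5.44 h), and at 7.43 h in SE21s, where its rhythm missed the threshold. These times come from 1 cosine curve on log2 values and need not match the hour of the highest value. In SE21s the highest means were at 3 h for PRR73 (281 FPKM), 6 h for PRR37 (198 FPKM) and 9 h for PRR95 (312 FPKM). The measured order of these genes was thus the reverse of the fitted one. GI followed at 8.76 to 9.02 h and the blue light receptor gene FKF1 at 10.6 to 10.9 h. PRR1/TOC1 peaked at 11.4 h in SE21s and 12.2 h in the other lines, LUX/PCL1 at 12.7 to 13.9 h, ELF3-2 at 15 h in SE21s and 16.8 h in LY2186, and ELF3-1 at 21.8 to 22.1 h.

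These rhythms were large. LHY cycled 1150-fold from trough to peak in SE21s, 2010-fold in LY2186 and 1860-fold in MH86, and GI 1480-fold in SE21s and 1170-fold in MH86. By limma, 11 clock genes of 13 passed the rhythm test in SE21s, 12 in LY2186 and 13 in MH86. The counts adjusted over the list alone were 12, 12 and 13, and 7 chlorophyll breakdown genes in SE21s, while the counts of the other lists stayed as given here. PRR59 missed the threshold in SE21s (adjusted p = 0.0506). LOC_Os06g47890, a ZTL-like gene, missed it in SE21s (0.633) and LY2186 (0.967) and passed in MH86 (0.0423), while the second ZTL-like gene, LOC_Os02g05700, passed in each line with a peak at 0.326 to 0.903 h.

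**Figure D1:**
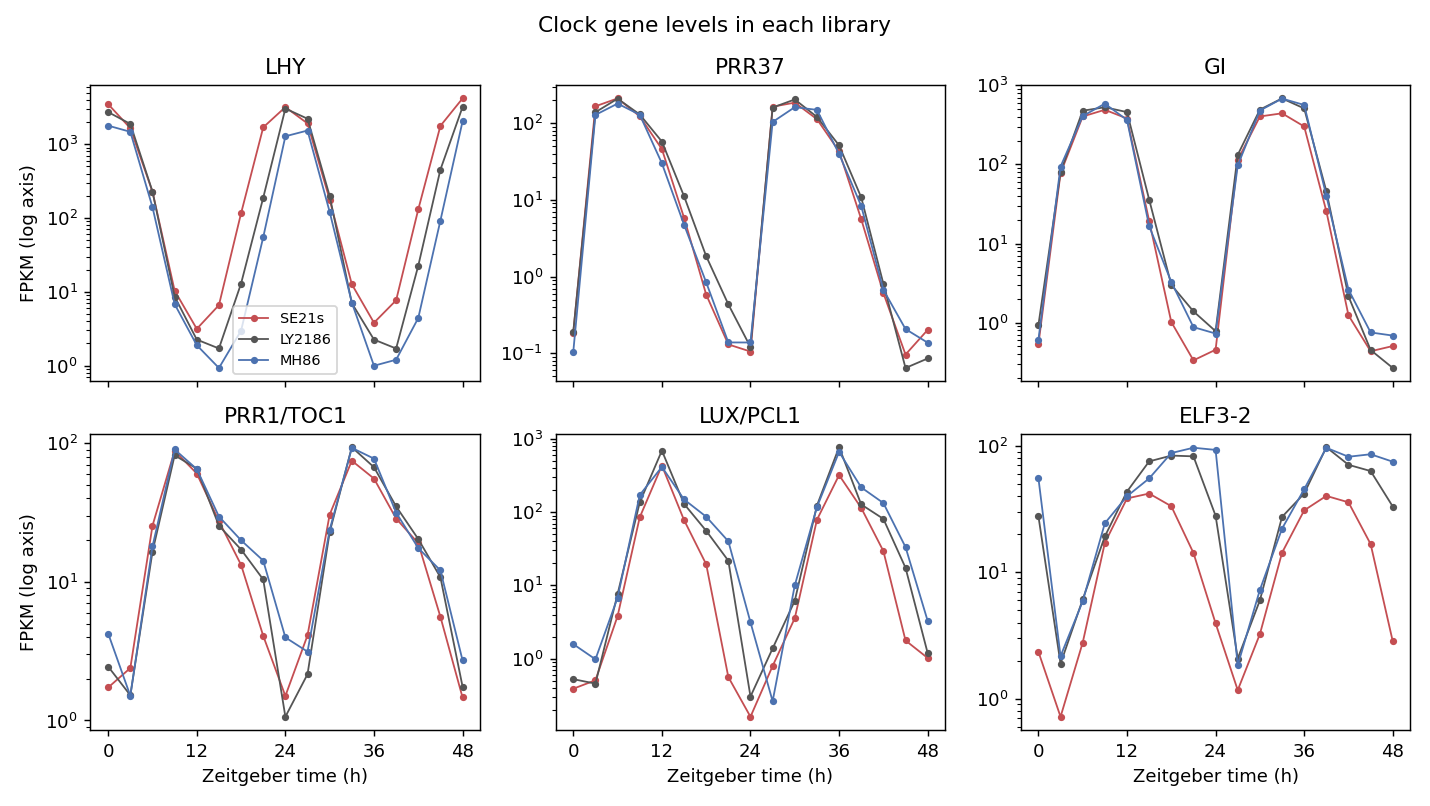
FPKM of 6 clock genes (log axis) against Zeitgeber time in hours, with 1 point per library and 1 line for each of SE21s, LY2186 and MH86. LHY rises earliest in SE21s, with 1692 FPKM at ZT21 against 189 in LY2186 and 55.0 in MH86, while ELF3-2 reaches lower levels in SE21s.

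All 13 antenna genes, which encode light-harvesting proteins of the photosystems, were rhythmic in each line, with mean peaks at 5.24 h in SE21s, 6.07 h in LY2186 and 6.8 h in MH86. CAB1R, LHCB2, LHCB3 and LHCB5 had the smallest adjusted p of the list in LY2186, and CAB1R cycled 1440-fold in SE21s. Of 12 chlorophyll synthesis genes, 11, 12 and 12 were rhythmic in SE21s, LY2186 and MH86, among them CHLH, a magnesium chelatase subunit, at 4.15, 5.22 and 5.67 h, CAO1, CRD1 and PORA. Of 11 carbon fixation genes, 8, 8 and 9 were rhythmic, including FBA, PRK, GAPB and GAPA. RCA, which encodes Rubisco activase, was not called, but 7 of its 51 values are listed at 0, at ZT24, ZT27 and ZT48 in SE21s and at ZT3 and ZT27 in the other lines. It stood at 24000 FPKM in SE21s, 11800 in LY2186 and 6440 in MH86 at ZT0.

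GBSSII, a granule-bound starch synthase of leaves, peaked at 1.93 h in SE21s, 3.24 h in LY2186 and 4.51 h in MH86, SSIIIb at 1.46, 2.45 and 3.42 h and SSIIb at 3.26, 3.71 and 4.29 h, and the debranching gene ISA1 peaked at 15.7 to 16.1 h. Of 12 starch synthesis genes, 9, 10 and 9 passed in SE21s, LY2186 and MH86. Of 9 starch breakdown genes, 8, 8 and 7 passed, with GWD1, PHO1, PHOH and the phosphatase gene SEX4 between 6.75 and 11.5 h. Sucrose genes passed in 9 of 11 cases in each line, with SPS1, SPS6, SUT2 and SUT4 between 22.2 and 4.18 h.

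In the flowering list 6 of 7 genes were rhythmic in each line. Hd1, a CONSTANS homologue, peaked at 15.9 h in SE21s and 16.4 h in LY2186, COL4 at 0.485 to 2.22 h, and the florigen gene Hd3a at 1 to 4.16 h. Photoreceptor genes passed in 5, 4 and 4 of 6 cases, among them CRY1b, PHYB and CRY2. Nitrogen genes passed in 4, 6 and 6 of 8 cases, with GS1;1, GS2, GS1;2 and NIA1 in each line. Chlorophyll breakdown genes passed in 6, 8 and 8 of 8 cases, including PAO, NYC3, NAP and SGR. Heat shock genes passed in 4, 5 and 4 of 6 cases, including HSFA2d, HSFA2c and LOC_Os02g52150. Of 7 defence genes, 2, 4 and 4 passed, and NPR1 passed in each line.

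Over all genes, limma called 11362 genes rhythmic in SE21s (67.5%), 11974 in LY2186 (71.1%) and 12149 in MH86 (72.1%), and 9162 genes (54.4%) in all 3 lines. With a trough-to-peak change of at least 2-fold the counts were 6980, 7790 and 7687. Most genes cycled, and no list held more rhythmic members than the other genes by Fisher's exact test after adjustment, the antenna list included (adjusted p = 0.11, 0.2 and 0.13 in SE21s, LY2186 and MH86). A further 833, 548 and 948 genes passed in SE21s, LY2186 or MH86 alone. Of the 548 in LY2186, 11 differed in rhythm from the mid-parent.

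**Figure D2:**
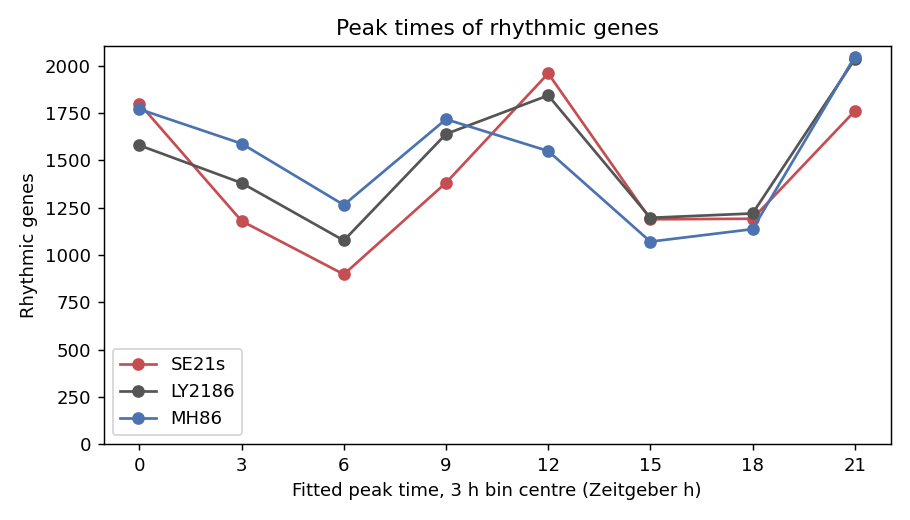
Number of rhythmic genes (limma) by fitted peak time in 3 h bins, in Zeitgeber hours, with 1 line for each of SE21s, LY2186 and MH86. The bin centred on 12 h holds 1960 genes in SE21s, 1844 in LY2186 and 1550 in MH86, and the bin centred on 3 h holds 1180, 1381 and 1589.

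The parents were compared for mean level over the day. SE21s leaves held more mRNA for the photosynthetic machinery than MH86 leaves. All 13 antenna genes were higher in SE21s, with a median log2 difference of 3.04, and so were all 12 chlorophyll synthesis genes (median 1.56) and 10 of 11 carbon fixation genes (median 1.17). The log2 mean gives much weight to hours of low expression, and the median ratio of day means in FPKM was 2.49 for antenna, 2.42 for chlorophyll synthesis and 2.22 for carbon fixation genes. Examples are LHCB4 (mean 2080 against 607 FPKM, log2 difference 3.46 ± 0.34 SE), LHCB6 (3.48 ± 0.36), LHCA5 (1.43 ± 0.12) and PSBS1, the photoprotection gene (2.13 ± 0.23). In chlorophyll synthesis HEMA1, which starts the pathway, stood at 247 against 75.6 FPKM (1.75 ± 0.11), and CHLI (1.44 ± 0.12), CHLD (0.91 ± 0.08) and PORB (1.74 ± 0.16) were higher too.

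In carbon fixation PGK (1.75 ± 0.12), GAPA (2.29 ± 0.20), GAPB (1.46 ± 0.14) and the Rubisco small subunit gene RBCS3 (1.05 ± 0.10) were higher in SE21s. Antenna and small subunit genes belong to families of similar copies, so reads may have been shared among members. These lists kept their direction with median-ratio and quantile scaling, with antenna medians of 3.12 and 2.81. Of 12 starch synthesis genes, 10 were higher in SE21s and 1 was lower. AGPL3 (1.09 ± 0.08), AGPS1 (0.87 ± 0.10), SSI (1.48 ± 0.17) and GBSSII (2.58 ± 0.35) had the smallest adjusted p. Camera with the preset correlation separated the chlorophyll synthesis (adjusted p = 3.2e-07), antenna (1.3e-06), carbon fixation (4.2e-06) and starch synthesis (0.0021) lists from other genes. With an estimated correlation the adjusted p values were 0.19, 0.31, 0.21 and 0.31.

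Single genes of other lists were lower in SE21s than in MH86, while camera with the preset correlation called none of these lists (adjusted p = 0.28 for chlorophyll breakdown, 0.19 for defence and 0.76 for flowering). Of 8 chlorophyll breakdown genes, 6 were lower, among them RCCR1 (43.2 against 108 FPKM, -1.36 ± 0.13), NYC3 (-0.98 ± 0.11), PAO (-0.32 ± 0.08) and SGR, the stay-green gene (-0.77 ± 0.26). Of 7 defence genes, 5 were lower, with PR1b at 0.0346 against 16.1 FPKM (-4.58 ± 0.30), NPR1, a salicylic acid co-receptor (-1.14 ± 0.12), PR10b (-2.69 ± 0.29) and PR10a/PBZ1 (-1.16 ± 0.23), and WRKY45 was higher in SE21s (chosen after its values were seen, 1.01 ± 0.21). PR10 genes are near-identical copies, so their split is uncertain. In the flowering list 4 of 7 genes were lower in SE21s and 2 were higher. The florigen gene Hd3a stood at 10.3 against 58.4 FPKM (-1.97 ± 0.28), its activator Ehd1 at 0.0562 against 2.17 FPKM (-1.31 ± 0.27), Ehd3 was lower (-0.23 ± 0.06) and COL4 higher (0.68 ± 0.21).

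In the nitrogen list ASN1, an asparagine synthetase gene, stood at 0.283 FPKM in SE21s and 21.6 in MH86 (-4.28 ± 0.35). NADH-GOGAT1 (-1.42 ± 0.16) and the nitrite reductase gene NiR (-1.98 ± 0.47) were lower too, and plastid GS2 was higher (0.95 ± 0.10). Of 8 nitrogen genes 2 were higher and 3 lower. Of 13 clock genes, 5 were lower in SE21s, among them ELF3-2 (-1.64 ± 0.25), PRR59 (-0.61 ± 0.10) and LUX/PCL1 (-1.46 ± 0.27), and LHY was higher (1.89 ± 0.30, at 17 of 17 times). Of 6 photoreceptor genes 3 were lower and 1 higher, with CRY2 (-0.69 ± 0.09), PHYC (-0.41 ± 0.08), CRY1b (-0.19 ± 0.05) and CRY1a (0.21 ± 0.06). Of 11 sucrose genes 4 were higher, such as SPS11 (0.79 ± 0.11) and SPS1 (0.73 ± 0.12), and 4 lower, such as SUS1 (-1.34 ± 0.14) and SPS2 (-0.26 ± 0.05). The sucrose median was -0.15 while camera pointed up (adjusted p = 0.99).

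Of 9 starch breakdown genes, 4 were higher in SE21s, including MEX1, a plastid maltose exporter (1.30 ± 0.06), PHOH (0.91 ± 0.12) and ISA3 (0.44 ± 0.07), and DPE1 was lower (-0.27 ± 0.08). Of 6 heat shock genes 2 were higher and 3 lower, with HSFA2d (1.27 ± 0.12) and HSFA2c (-0.51 ± 0.08) on opposite sides. Adjusted over each list alone, the counts were as above, except that 5 sucrose genes were lower. Over all genes limma called 11624 genes between SE21s and MH86 (69%), 4824 higher and 6800 lower in SE21s, of which 2329 differed by at least 2-fold. Higher genes made up 41.5% of calls, against 49.8% with median-ratio and 46.9% with quantile scaling, so the imbalance depends on the scaling. Outside the lists, LOC_Os02g12480 (971 against 0.328 FPKM) and LOC_Os04g12920 (2700 against 121 FPKM) were higher in SE21s, and LOC_Os08g08655 (0.0844 against 302 FPKM) and LOC_Os04g02670 (405 against 12400 FPKM) were lower. LOC_Os04g12920 and LOC_Os04g02670 hold 2 and 4 doubtful zeros, and with these set missing they passed with 2700 against 137 and 492 against 12400 FPKM. Without the time block the count was 6810.

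**Figure D3:**
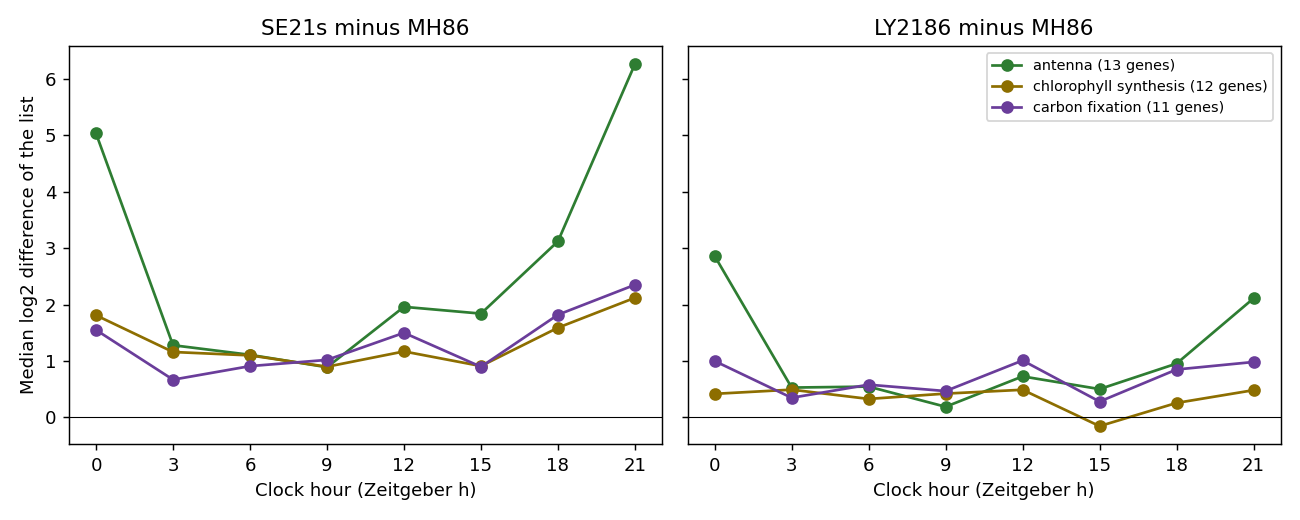
Median log2 difference of 3 gene lists at each clock hour (Zeitgeber h), SE21s minus MH86 on the left and LY2186 minus MH86 on the right, with 2 libraries per line and hour (points are medians over the list). The antenna difference between the parents runs from 0.89 at 9 h to 6.26 at 21 h.

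The hybrid was then compared with SE21s. LY2186 held less photosynthetic mRNA than its male-sterile parent. All 13 antenna genes were lower (median -1.89), as were all 12 chlorophyll synthesis genes (median -1.03), 10 of 11 carbon fixation genes (median -0.53) and 9 of 12 starch synthesis genes (median -0.53). In day means of FPKM the median ratios to SE21s were 0.578, 0.504, 0.721 and 0.747 in this order, so the antenna difference is smaller on that scale. LHCB4 stood at 1020 against 2080 FPKM (-1.96 ± 0.34), with CAB2R (-2.15 ± 0.36), PSBS1 (-1.34 ± 0.23) and LHCA5 (-0.78 ± 0.12). GSA (-1.07 ± 0.10), YGL1 (-0.86 ± 0.09), HEMA1 (-1.02 ± 0.11), PORB (-1.40 ± 0.16), PGK (-0.92 ± 0.12), GAPB (-0.85 ± 0.14), GAPA (-1.17 ± 0.20) and SBPase (-0.57 ± 0.12) were lower as well, and so were AGPS1 (-1.18 ± 0.10), SSI (-1.61 ± 0.17), AGPL3 (-0.59 ± 0.08) and GBSSII (-1.97 ± 0.35).

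Single defence, nitrogen and flowering genes were higher in LY2186, while camera with the preset correlation called none of these lists (adjusted p = 0.13, 0.92 and 0.49). Of 7 defence genes 4 were higher than in SE21s, PR10b (2.99 ± 0.29), PR1b (2.91 ± 0.30), NPR1 (1.02 ± 0.12) and PR10a/PBZ1 (1.54 ± 0.23), and 1 was lower. ASN1 stood at 19.5 against 0.283 FPKM (4.33 ± 0.35), NADH-GOGAT1 was higher (1.09 ± 0.16) and GS2 lower (-0.45 ± 0.10), which made 2 of 8 nitrogen genes higher and 1 lower. Hd3a (1.94 ± 0.28), Ehd1 (1.02 ± 0.27) and MADS51 (0.21 ± 0.06) were higher and Hd1 lower (-0.36 ± 0.13), 3 and 1 of 7 genes. Of 13 clock genes 8 were higher, among them ELF3-2 (1.36 ± 0.25), PRR59 (0.47 ± 0.10), GI (0.46 ± 0.10) and ELF3-1 (0.21 ± 0.05), and LHY was lower (-0.98 ± 0.30, chosen after its values were seen). CRY2 (0.74 ± 0.09), CRY1b (0.32 ± 0.05) and PHYC (0.45 ± 0.08) were higher, 3 of 6 photoreceptor genes.

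RCCR1 (0.69 ± 0.13) and NYC3 (0.42 ± 0.11) were higher in LY2186 and SGR (-0.70 ± 0.26) and NAP (-0.35 ± 0.15) lower, in a list with 3 of 8 genes higher and 2 lower. Of 11 sucrose genes 3 were higher, SUS1 (0.88 ± 0.14), SPS2 (0.25 ± 0.05) and SWEET13 (1.07 ± 0.30). Of 9 starch breakdown genes 4 were lower, MEX1 (-0.75 ± 0.06), ISA3 (-0.47 ± 0.07), PHOH (-0.74 ± 0.12) and SEX4 (-0.25 ± 0.05). Of 6 heat shock genes 3 were higher, such as HSP81-1 (0.53 ± 0.11), and 2 lower, HSP101 (-0.43 ± 0.09) and HSFA2d (-0.61 ± 0.12). Adjusted over the list alone, 1 more clock gene was higher and 1 more defence gene lower.

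Camera with the preset correlation called 5 lists lower in LY2186 than in SE21s: chlorophyll synthesis (adjusted p = 8.2e-08), antenna (1.8e-05), starch synthesis (0.00037), carbon fixation (0.0011) and starch breakdown (0.017). With an estimated correlation the adjusted p values were 0.15, 0.35, 0.26, 0.35 and 0.35. For nitrogen, heat shock and floral organ genes the median, the mean and the camera direction differed in sign, and none passed. Over all genes limma called 9640 (57.2%), with 57.3% of them higher in LY2186, a share of 48% with median-ratio and 47% with quantile scaling. Outside the lists, LOC_Os08g08655 (180 against 0.0844 FPKM) and LOC_Os07g13234 (78.5 against 0.07 FPKM) were higher, and LOC_Os05g47540 (12.3 against 120 FPKM) and LOC_Os07g04270 (31.6 against 218 FPKM) lower. LOC_Os07g04270 holds 1 doubtful zero, and with it set missing passed with 33.6 against 218 FPKM. Without the time block the count was 4090.

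Against MH86 the hybrid showed the reverse for photosynthesis. In LY2186, 10 of 13 antenna genes (median 1.05), 10 of 11 carbon fixation genes (median 0.70) and 6 of 12 chlorophyll synthesis genes (median 0.36) were higher than in its restorer parent, and none was lower. The median ratios of day means in FPKM were 1.42, 1.61 and 1.3. Among them were LHCB4 (1.5 ± 0.34), LHCA2 (1 ± 0.24), LHCB6 (1.38 ± 0.36), LHCA5 (0.65 ± 0.12), RBCS4 (0.89 ± 0.12), RBCS3 (0.65 ± 0.10), RBCS2 (1.19 ± 0.18), PGK (0.83 ± 0.12), HEMA1 (0.73 ± 0.11), CHLH (0.93 ± 0.22), CHLI (0.39 ± 0.12) and CHLD (0.28 ± 0.08). Of 8 chlorophyll breakdown genes 5 were lower, with SGR at 8.13 against 17.1 FPKM (-1.46 ± 0.26), RCCR1 (-0.67 ± 0.13), NYC3 (-0.55 ± 0.11) and the senescence regulator NAP (-0.71 ± 0.15).

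In the nitrogen list NiR stood at 10.3 against 59.4 FPKM (-2.28 ± 0.47), NIA1 was lower (-1.04 ± 0.39) and GS2 higher (0.50 ± 0.10). PR1b (-1.67 ± 0.30) and WRKY76 (-0.53 ± 0.20) were lower, while the other 5 defence genes did not pass. COL4 was the flowering gene that passed (0.56 ± 0.21), with 6 of 7 not called. Of 13 clock genes 4 were higher, ELF3-1 (0.21 ± 0.05), PRR73 (0.25 ± 0.07), PRR37 (0.29 ± 0.09) and LHY (0.91 ± 0.30), and of 6 photoreceptor genes CRY1a (0.18 ± 0.06). MEX1 (0.55 ± 0.06), AGPL3 (0.50 ± 0.08), SPS11 (0.63 ± 0.11) and SPS1 (0.48 ± 0.12) were higher, and DPE1 (-0.43 ± 0.08), AGPS1 (-0.31 ± 0.10), ISA1 (-0.27 ± 0.08), SSIVb (-0.28 ± 0.10), SUS1 (-0.47 ± 0.14) and SPS8 (-0.25 ± 0.09) lower. In starch synthesis 2 genes were higher and 3 lower, in starch breakdown 1 and 1, in sucrose 2 and 2, and in heat shock 1 and 3, with HSFA2d (0.65 ± 0.12) higher and HSFA2c (-0.25 ± 0.08) and HSP81-1 (-0.29 ± 0.11) lower.

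Adjusted over the list alone, 11 antenna and 7 chlorophyll synthesis genes were higher, and no flowering gene passed. Camera with the preset correlation called the carbon fixation (adjusted p = 4.8e-06), antenna (5e-04) and chlorophyll synthesis (0.0074) lists higher, and with an estimated correlation the adjusted p values were 0.35, 0.68 and 0.68. Over all genes limma called 5462 (32.4%), 2501 higher and 2961 lower in LY2186. The share of higher genes, 45.8%, was 50% with median-ratio and 40.9% with quantile scaling. LOC_Os02g12480 (583 against 0.328 FPKM) and LOC_Os04g12920 (1360 against 121 FPKM, or 137 with its 2 doubtful zeros set missing) were higher, and LOC_Os01g64120 (12.6 against 147 FPKM) and LOC_Os12g36860 (34 against 189 FPKM) lower. Without the time block the count was 1490, and with the first or the second day alone it was 2475 or 2237.

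The next comparison set the hybrid against the mean of its parents. Most list genes were not called against it: 0 of 13 antenna genes passed by limma (0 at an unadjusted p under 0.05), and 1 of 11 carbon fixation genes, RBCS4 (0.30 ± 0.10). The antenna median was -0.36, so a modest departure is not excluded. In day means of FPKM each antenna gene lay below the mean of the parents. CAB2R, for example, stood at 935 FPKM in LY2186, 2380 in SE21s and 514 in MH86. The departure on that scale was not tested. In chlorophyll synthesis 6 of 12 genes lay below and 6 did not pass, with a list test that was lost under an estimated correlation (adjusted p = 0.38). Those below included GSA (-0.52 ± 0.09), YGL1 (-0.36 ± 0.08), PORB (-0.53 ± 0.14) and PORA (-0.55 ± 0.14). In starch synthesis AGPS1 (-0.75 ± 0.08), SSI (-0.87 ± 0.15) and ISA1 (-0.33 ± 0.07) lay below, 3 of 12 genes, and in starch breakdown SEX4 (-0.18 ± 0.04), DPE1 (-0.30 ± 0.07), ISA3 (-0.25 ± 0.06) and PHOH (-0.28 ± 0.11), 4 of 9 genes. SGR (-1.08 ± 0.23) and NAP (-0.53 ± 0.13) lay below, 2 of 8 chlorophyll breakdown genes.

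Above the mid-parent were ASN1 (2.19 ± 0.30), PR10b (1.65 ± 0.25), PR10a/PBZ1 (0.96 ± 0.20), NPR1 (0.46 ± 0.10), Hd3a (0.96 ± 0.24), MADS51 (0.14 ± 0.05), CRY2 (0.40 ± 0.08), CRY1b (0.23 ± 0.05), PHYC (0.25 ± 0.07) and SPS2 (0.12 ± 0.04). Of 13 clock genes 6 were above, among them ELF3-1 (0.21 ± 0.04), PRR73 (0.20 ± 0.06), PRR37 (0.26 ± 0.08) and LOC_Os02g05700 (0.15 ± 0.05), and none was below. NADH-GOGAT1 was above (0.38 ± 0.14), NiR (-1.29 ± 0.41), NIA1 (-0.88 ± 0.34), WRKY45 (-0.53 ± 0.19) and HSP101 (-0.21 ± 0.07) below. In all, 3 of 7 defence genes were above and 2 below, 2 of 8 nitrogen genes each way, 2 of 7 flowering and 3 of 6 photoreceptor genes above, 1 of 11 sucrose genes above and 1 of 6 heat shock genes below. Adjusted over the list alone, 8 chlorophyll synthesis genes were below, 7 clock and 4 defence genes above, and the sucrose, heat shock and carbon fixation calls were lost.

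Camera with the preset correlation called chlorophyll synthesis (adjusted p = 0.00084), starch synthesis (0.0069) and starch breakdown (0.02) lower than mid-parent, with an adjusted p of 0.38 for each under an estimated correlation. In the heat shock and grain storage lists the median and the camera direction differed in sign, and neither passed. Over all genes limma called 4513 (26.8%), 2746 above and 1767 below the mid-parent. Above made up 60.8% of calls, against 54% with median-ratio and 46.1% with quantile scaling. Of 351 genes with at least a 2-fold departure, 329 were above and 22 below. This excess is largely set by the scale, since a hybrid at the mean of the parents in FPKM lies above their mean in log2. Against the mean in FPKM, 2530 of the 4513 called genes lay above and 1983 below, and 62 and 60 of them were at least 2-fold above and below. Without the time block 778 genes were called, and the first and second day alone gave 1819 and 1183.

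Among the 11624 genes that differed between the parents, the hybrid mean lay between them for 78.5%. It differed from SE21s alone for 47.1%, from MH86 alone for 14.6%, from both for 25.3% and from neither for 13%. Beyond both parents lay 385 genes above and 319 below, of which 28 and 1 did so by at least 2-fold. Quantile scaling gave 302 above and 673 below, so which side is larger depends on the scaling. From the lists, the clock genes PRR37 and ELF3-1 were above both parents, and SGR, NAP, AGPS1 and ISA1 below both. As the 2 contrasts share the LY2186 libraries, unchanged groups were simulated 20 times, which gave 0 genes in either direction. With no line differing, few genes can pass either contrast, so this 0 was set largely in advance. It does not test a hybrid equal to 1 parent or between the parents. Independent lists of these sizes would share 819.9 genes above and 724 below. With LY2186 libraries split between alternate time points, 90 and 90 genes lay above and 40 and 47 below, against 214 and 397 and against 193 and 282 for independent lists. Without the time block 57 and 13 genes were called.

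The next comparisons asked whether the daily curve itself differed, in amplitude, in peak time or in both. At clock hour 21, LHY stood at 1730 ± 57 FPKM in SE21s, 321 ± 190 in LY2186 and 73.8 ± 27 in MH86 (SD, n = 2 each), and its fitted peak in SE21s minus that in MH86 was -1.54 h (limma adjusted p = 4.88e-07). ELF3-2, an evening complex gene, stood at 15.4 ± 1.8, 72.7 ± 14 and 91 ± 7.6 FPKM at that hour, with a peak difference of -2.72 h (2.03e-05). The fitted difference was -1.2 h for its partner LUX/PCL1 (0.00817) and -0.75 h for PRR1/TOC1 (0.012). Their highest means stayed at 12 h and 9 h in all 3 lines. At hour 21 LUX/PCL1 stood at 1.16 FPKM in SE21s and 36.7 in MH86, and PRR1/TOC1 at 4.84 and 13.2. ELF3-1 differed as well (0.041), with a log2 amplitude of 0.539 in SE21s and 0.734 in MH86. Its peak difference of -0.291 h was smaller than the SE of either peak (0.44 and 0.49 h). PRR59 differed by 1.99 h in the other direction (0.00273), though its rhythm missed the threshold in SE21s. PRR59 was highest at 9 h in each line, and at hour 0 stood at 19.4 FPKM in SE21s and 52.1 in MH86. In all 6 of 13 clock genes passed, while PRR37, PRR73, PRR95, GI, FKF1, LOC_Os06g47890 and LOC_Os02g05700 did not.

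All 7 flowering genes differed in rhythm between SE21s and MH86 (adjusted p = 0.00088 by Fisher's exact test against other genes). That test takes genes as independent, which members of a list may not be. The peak difference (SE21s minus MH86) was -3.16 h for Hd3a and -1.47 h for Hd1, while MADS51 differed by 3.67 h, and Ehd1 was near the floor in SE21s. Hd3a belongs to a gene family, so how reads were divided within it is uncertain. In the antenna list 12 of 13 genes differed (Fisher's exact test, adjusted p = 2.7e-05), with peak differences of -1.38, -1.08, -1.35 and -2.7 h for LHCA1, LHCA4, LHCB4 and LHCB6. The antenna median was -1.39 h, with a median log2 amplitude ratio of -0.57. Of 12 chlorophyll synthesis genes 8 differed, and of 12 starch synthesis genes 8 (Fisher's exact test, adjusted p = 0.02 each), with peak differences of -1.51, -3.06, -1.6 and -2.73 h for CHLH, CRD1, CAO1 and PORB, and of -2.58 and -1.96 h for GBSSII and SSIIIb. BEIIa and SSI passed too.

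The other lists did not pass Fisher's exact test (adjusted p from 0.49 to 1), though some held larger shares than the 27.5% of other genes. Of 11 carbon fixation genes 5 differed, with PRK (-1.77 h), FBA, PGK and SBPase, as did 4 of 8 chlorophyll breakdown genes, with NYC1, NAP, RCCR1 and Osl2, and 4 of 9 starch breakdown genes, with PHOH, DPE2, PHO1 and BAM2. Of 8 nitrogen genes 3 (GS1;1, GS2 and NADH-GOGAT1) passed, and 1 each of the sucrose (SPS1), photoreceptor (PHYC), heat shock (HSFA2c) and defence (WRKY45) lists. In counts adjusted over the list alone, 13 antenna and 9 starch synthesis genes passed. Across all genes tested limma called 4627 (27.5%), and 1386 without the time block.

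The hybrid's rhythms were set against each parent in the same way. Against SE21s, the fitted peak of LHY was 1 h later in LY2186 (limma adjusted p = 0.000709), that of ELF3-2 1.85 h later (0.00453) and that of PRR37 0.34 h later (0.0243). The shift of PRR37 was smaller than the SE of its peak in either line (0.36 and 0.39 h). The other 10 clock genes did not pass. In LY2186, 8 of 13 antenna genes (Fisher's exact test, adjusted p = 0.00066), 6 of 12 chlorophyll synthesis genes (0.014) and 4 of 7 flowering genes (0.032) differed. LHCA4, LHCA1, LHCB3 and LHCB6 peaked 0.511, 0.73, 0.789 and 1.54 h later in LY2186, CHLH, CAO1 and CRD1 1.06, 0.957 and 1.74 h later, and Hd3a and Hd1 2.34 and 0.539 h later. Ehd1 passed too, but its rhythm did not pass in SE21s (adjusted p = 0.199), so its shift is poorly set. YGL1 differed too (0.000353), with a log2 amplitude of 0.415 in SE21s and 0.948 in LY2186. Its fitted peak was 0.993 h earlier in LY2186, with an SE of 1.1 h in SE21s. Of 11 chlorophyll synthesis genes rhythmic in both lines, 5 peaked earlier in LY2186. GBSSII (1.3 h later), BEIIa, AGPS2 and SSIIIb passed in starch synthesis, 4 of 12 genes. PHOH, ISA3, NYC1, RCCR1, PRK, HSFA2c and PR1b passed in their lists, and no photoreceptor, sucrose or nitrogen gene did by limma (2 of 6, 1 of 11 and 2 of 8 at an unadjusted p under 0.05). Adjusted over the list alone, 7 clock, 11 antenna, 9 chlorophyll synthesis, 3 chlorophyll breakdown, 3 starch breakdown and 1 photoreceptor genes passed.

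Against MH86, 6 of 13 antenna genes differed in rhythm (Fisher's exact test, adjusted p = 3.5e-06). No clock gene passed by limma, while 4 of 13 had an unadjusted p under 0.05. The peak in LY2186 minus that in MH86 was -0.791, -0.825, -0.653 and -1.16 h for LHCB4, LHCA2, LHCA1 and LHCB6, and -1.32 h for CRD1. GBSSII, AGPL3 and SSIIIb passed, 3 of 12 starch synthesis genes (Fisher's exact test, adjusted p = 0.018, though the rhythm of AGPL3 itself passed in neither line), as did MADS51, Hd1 and HSFA2c. Adjusted over the list alone, 8 antenna, 5 flowering, 4 chlorophyll synthesis, 2 defence, 1 nitrogen and 0 clock genes passed. Against the mid-parent rhythm, YGL1 (adjusted p = 0.0413) and GBSSII (0.046) were the list genes that passed. Adjusted over the list alone, 3 chlorophyll breakdown, 2 starch synthesis, 1 chlorophyll synthesis and 1 heat shock genes passed.

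Across the genes tested, limma called rhythm differences for 2116 genes between LY2186 and SE21s (12.6%), 393 between LY2186 and MH86 (2.33%) and 136 between LY2186 and the mid-parent (0.808%). With 1 time point left out the last 2 counts ranged from 170 to 562 and from 51 to 183. The counts were 291, 71 and 13 without the time block. When line labels were swapped within time points, up to 5165 genes passed for LY2186 against SE21s and 7660 for SE21s against MH86. With line means removed before the swaps, a step added after that result was seen, the highest counts were 182 and 3996.

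Over the 7370 rhythmic genes as a whole, fitted peaks came earlier in SE21s than in MH86. The median difference was -0.463 h (permutation p = 0.0198), and 65% of genes peaked earlier in SE21s, 33% by more than 1 h. Genes that peak between 21 and 3 h had a median of -0.822 h, and those between 9 and 15 h one of -0.0931 h. Without ZT24 or ZT45 the p was 0.0594 in each case, with medians of -0.451 and -0.382 h. The median difference was -0.357 h for LY2186 minus MH86 (permutation p = 0.0594) and 0.166 h for LY2186 minus SE21s (0.426), and neither passed. Amplitudes were 1.08 times those of SE21s in LY2186 (permutation p = 0.0297, and 0.0594 without ZT3), 1.04 times those of MH86 (0.426), and in SE21s 0.965 times those of MH86 (0.287).

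**Figure D4:**
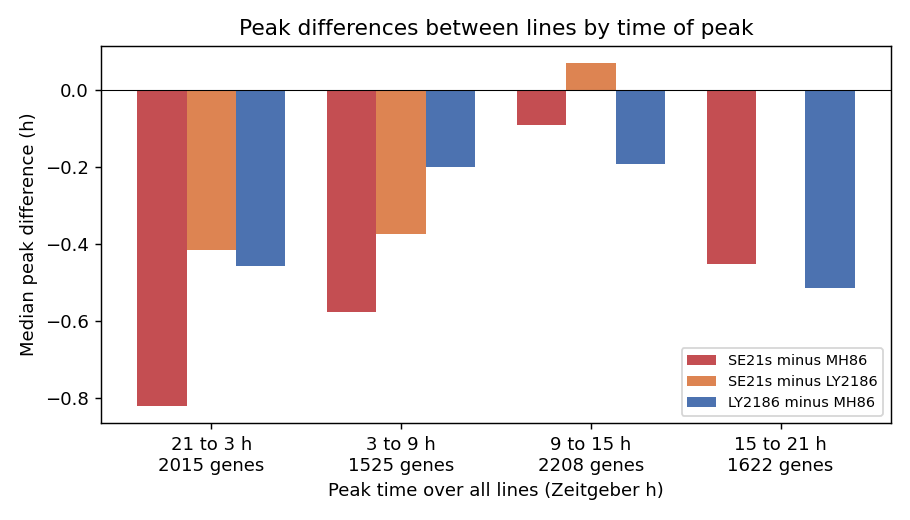
Median difference in fitted peak time (h) between pairs of lines, for genes grouped by peak time over all lines (Zeitgeber h), with line means removed. SE21s minus MH86 is -0.822 h for 2015 genes that peak between 21 and 3 h and -0.0931 h for 2208 genes that peak between 9 and 15 h.

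Markers of other organs were also read. In the grain list the glutelin genes GluA1 and GluA2 had means of 0.915 to 2.26 and 3.26 to 3.58 FPKM, the other 5 genes were below the filter, and neither tested gene passed between lines. Of the 5, GluA3 had a mean of 0.393 FPKM but reached 14.9 FPKM in 1 library. In the floral list MADS1 stood at 2.01, 4.51 and 8.28 FPKM in SE21s, LY2186 and MH86 and was lower in SE21s than in MH86 (-1.23 ± 0.21). MADS16 stood at 16.8, 11.1 and 8.81 FPKM, in SE21s and LY2186 above the upper quartile of any library. MADS16 (0.88 ± 0.09) and MADS3 (0.73 ± 0.13) were higher in SE21s than in MH86, and 4 floral genes were below the filter. Against SE21s, MADS1 was higher (0.76 ± 0.21) and MADS16 lower (-0.52 ± 0.09) in LY2186, and against MH86, MADS16 (0.36 ± 0.09) and MADS3 (0.57 ± 0.13) were higher.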

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

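The label swaps within time points for rhythm differences, the time shuffles for rhythmic genes, and the peak-time tests of a shifted sampling time and of a single failed library were chosen only after the results were seen.

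A difference between lines in the daily curve, tested as an interaction, singled out 2116 genes for LY2186 against SE21s, 393 for LY2186 against MH86, 4627 for SE21s against MH86 and 136 for LY2186 against the mid-parent. With line labels swapped within time points, 7 of 100 splits gave as many genes for LY2186 against SE21s (2116, highest other 5165) and 5 of 100 for SE21s against MH86 (4627, highest other 7660), so these swaps do not exclude chance. For LY2186 against MH86 the count was 4 of 100 (393, highest other 1468), and for the mid-parent 2 of 100 (136, highest other 613). These counts are under 5 of 100, but some of the same swaps called several times the real count. The raw swaps therefore do not settle the question of chance here either. Swaps that call several times the real count point to a structure of the samples. Level differences between lines may be part of it. For SE21s against MH86 they are not all of it, since up to 3996 genes still passed with line means removed. With line means removed first, 1 of 100 splits, the real one, gave as many genes in each case. The highest other counts were 182 (LY2186 against SE21s), 220 (LY2186 against MH86), 3996 (SE21s against MH86) and 8 (mid-parent). For the pairs of lines, this version alone argues against chance, and it was added after the raw swaps were seen. For SE21s against MH86 its margin was narrow (3996 against 4627). For the mid-parent, swaps mix parents that differ in rhythm, so they do not test a hybrid with the mid-parent rhythm. For the genes rhythmic in a line, 1 of 100 orders of the times, the real one, gave as many in SE21s (11362, highest other 2546), LY2186 (11974, highest other 2805) and MH86 (12149, highest other 3109). This argues against a chance order of the times for the counts. Shuffled orders still called up to 3109 genes, so single calls may be less certain than their adjusted p. Shuffling also breaks the likeness of neighbouring times, so it does not test a slow drift.

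The same test between SE21s and MH86 singled out clock and flowering genes, given here as fitted peak in SE21s minus fitted peak in MH86. It covers amplitude and peak time together, so these shifts were not tested alone. The values were -1.54 h for LHY, -0.75 h for PRR1/TOC1, 1.99 h for PRR59, -0.291 h for ELF3-1, -2.72 h for ELF3-2 and -1.2 h for LUX/PCL1. By measured means, PRR1/TOC1, PRR59 and LUX/PCL1 were each highest at the same clock hour in both lines. In the flowering list they included -1.47 h for Hd1, -3.16 h for Hd3a, -1.74 h for COL4 and 3.67 h for MADS51. For PRR59 and Ehd1 (-2.07 h) the rhythm did not pass in SE21s, and for Ehd3 (-3.83 h) it did not pass in LY2186 or MH86, so these 3 peak times are poorly set. Hd3a belongs to a gene family, so how reads were divided within it is uncertain.

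Fitted peaks came earlier in SE21s than in MH86 as a whole. Sampling of all SE21s libraries later than labelled would make peaks seem earlier, and would move genes of every peak time alike. Genes peaking at 21 to 3 h differed by -0.729 h from those at 9 to 15 h (permutation p = 0.0099, the smallest 100 draws can give), which argues against it. That test was first made with genes peaking at 3 to 9 h (-0.484 h, permutation p = 0.0495), short of the bound of 0.5 h set for it, and then with the 21 to 3 h genes. The groups compared last have the largest and smallest medians (-0.822 and -0.0931 h), and were picked after the values were seen. Genes peaking at 15 to 21 h had a median of -0.452 h, so the evidence is limited. A single failed library, a difference on 1 day and late sampling at ZT21 and ZT45 are argued against by medians nearest 0 of -0.409 h with 1 time point left out, -0.356 h with days fitted apart and -0.349 h without both times. The cause stays open, because line, plants and sampling order are not separated in 1 library per line and time. A shift of the whole clock is not shown, as PRR37 (-0.125 h), PRR73 (-0.04 h), PRR95 (0.181 h), GI (-0.183 h) and FKF1 (-0.307 h) did not pass in this comparison.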

How the results depend on the processing

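The alternatives that remove doubtful zeros, and line means removed before permuting, were chosen after seeing the data, while the others were planned. Over 39 settings and 23 results, 497 values kept their direction and side of the threshold, or stayed within 1.5 times the count, and 56 counts moved, 7 results passed a threshold they had missed, 3 fell short and 1 reversed. Where not stated, the cause was not tested.

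Stricter fold limits lower counts by construction. With a 2-fold minimum, rhythmic genes numbered 6980, 7790 and 7687 (SE21s, LY2186, MH86), level differences 1190 (LY2186 against SE21s), 619 (against MH86), 2329 (SE21s against MH86) and 351 (mid-parent), with 28 genes above and 1 below both parents. Without the time block the levels gave 4090, 1490, 6810 and 778, with 57 above and 13 below, and rhythm differences 291, 71, 1386 and 13. The first day alone gave 5566 for LY2186 against SE21s, 2475 against MH86 and 1819 for the mid-parent, with 191 above and 103 below. The second day gave 2237 and 1183 for the last pair, with 56 above and 38 below. No expression filter gave 588 genes above both parents, and quantile scaling 673 below. Rhythm differences from the mid-parent were 335 with quantile scaling, 209 with a trend per line and 64 with 12 h curves added. Without ZT48 those against MH86 and the mid-parent were 170 and 60. With an estimated correlation 0 lists passed in each of 4 level comparisons, against 5, 3, 4 and 3.

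The log2 amplitude ratio of SE21s to MH86 passed with quantile scaling (-0.103) and with a pooled 1.5-fold minimum (-0.0884), and reversed with 4-fold (0.0215, permutation p = 0.772). The peak difference of LY2186 and MH86 passed with line means removed (-0.357 h, permutation p = 0.0099).

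Leaving out each time point in turn, rhythm differences ranged from 170 to 562 for LY2186 against MH86 and from 51 to 183 for the mid-parent. The first moved by over 1.5 times without ZT0 (255), ZT9 (253), ZT12 (207), ZT24 (174), ZT33 (247) and ZT48 (170). The second did so without ZT0 (82), ZT6 (87), ZT9 (66), ZT12 (51), ZT15 (90), ZT18 (65), ZT24 (65), ZT33 (90), ZT36 (70), ZT39 (74) and ZT48 (60). The amplitude ratio of LY2186 to SE21s ranged from 0.0866 to 0.126 and fell short without ZT3 (0.0903, permutation p = 0.0594). The peak difference of SE21s and MH86 ranged from -0.497 to -0.382 h and fell short without ZT24 or ZT45 (permutation p = 0.0594 each). That of LY2186 and MH86 ranged from -0.39 to -0.304 h and passed without ZT6 (permutation p = 0.0495), ZT24 (0.0396), ZT27 (0.0297) and ZT30 (0.0198). Depth is unknown, so what it limits was not assessed.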

Other observations

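The tests of scaling, leaf age and spread between time points, and the label swaps for levels, were chosen only after the results were seen.

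The number of genes that differed between lines changed with the clock hour. Between SE21s and MH86, limma called 7321 genes at hour 21, 6291 at hour 0 and 2050 at hour 15. Between LY2186 and SE21s it called 5121 at hour 21, and between LY2186 and the mid-parent 1141 at hour 15, 1037 at hour 0 and 224 at hour 6. Exact zeros between high values were listed for 8 of 76 genes with a mean of at least 1000 FPKM (10.5%), and for 0.512% of genes between 100 and 1000 FPKM.

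Genes expressed in 1 parent alone (at least 5 FPKM, against under 0.1 in the other) stood in LY2186 at a median near the mean of the parents, with 2 of the SE21s genes and 5 of the MH86 genes above the parental level. The 114 genes of SE21s stood in the hybrid at a median of 51% of the parental level (quartiles 43.2% and 58.7%), and the 124 genes of MH86 at 49.4% (44.2% and 55.9%). The difference of -1.65 percent points had a permutation p of 0.34.

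Antenna and chlorophyll synthesis genes were higher in SE21s than in MH86. Scaling of the libraries is argued against by a lowest antenna median of 2.81 over 2 other scalings. An earlier rise of the same daily curve would put SE21s below MH86 at some hour, and the lowest median over the 8 clock hours was 0.89. Leaf age or stage may account for the pattern, since 6 of 8 chlorophyll breakdown genes were lower in SE21s, but age and line cannot be told apart because the labels give no leaf age apart from the line. A genetic difference between the parents stays open and untested.

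LY2186 lay nearer to MH86 than to SE21s. The slope of hybrid minus mid-parent on the distance from mid-parent to MH86 was 0.122 ± 0.0921 (SD, 17 times), positive at 16 times, with a sign-flip permutation p of 3e-05, which argues against spread between time points. Low values are argued against by a slope of 0.169 for genes of at least 20 FPKM. With the parental mean taken in FPKM the slope was 0.103 ± 0.102, and with the distance taken from the other day 0.135 ± 0.104 (both added later). More MH86 than SE21s RNA in the hybrid libraries is argued against by the -1.65 percent points above. The same value shows no lean to MH86 in genes expressed in 1 parent alone, so what accounts for the slope stays open.

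For the level comparisons, labels were swapped or permuted within time points. The real split alone of 100 gave as many genes for each pair of lines (1 of 100 each). The count was 9640 for LY2186 against SE21s (highest other 6222) and 5462 for LY2186 against MH86 (highest other 2683). For SE21s against MH86 it was 11624 (highest other 8806). For these pairs, a chance order of labels within times is argued against. Swapped labels still called up to 8806 genes, and no swap separates line from plants. For LY2186 against the mid-parent the real split alone of 100 also gave as many (4513, highest other 2). The real split alone of 51 gave as many genes above both parents (385, highest other 0) and below both (319, highest other 0), 1 of 51 each. In the mid-parent and both-parent tests, permuted labels mix the parents, whose differences then add to the spread. Few genes can then pass, so the highest others of 2 and 0 were set largely in advance. They do not test a hybrid at the mid-parent or equal to 1 parent.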
